A study of Mus musculus with 2 samples.

How the data were processed

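Total RNA from tibialis anterior muscle of 1 control mouse and 1 N2ICD-transgenic mouse was labelled with a single dye (Cy3), per the labels' protocols, and hybridised to 1 mouse array each. Groups were taken from the sample labels. The scanner files hold spot intensity values made by the authors with Agilent Feature Extraction 10.10.1.1, per the file headers: the processed intensity is background-subtracted and detrended within each array and not normalized between arrays, and spots not above background carry a small surrogate value. Probe coordinates are on mm9, per the file headers. The authors' deposited table holds an unsigned fold (ratio) with a direction per probe, an intensity per array and a normalized log2 value per array. How it was made is not given in the sources used here. In the authors' deposited table, 23793 of 23793 probes were flagged as detected on at least 1 array, and 21644 on both. Its intensity column was within 0.1% of the mean processed signal of the probe for 99.3% of probes on each array. Its log2 column was the log2 intensity minus a constant per array that corresponds to a signal of 149 for control and 166 for N2ICD, below which 75.0% of all probes lay.

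The main values were computed from the scanner files. The log2 processed signal of each spot was reduced by the array's 75th percentile over 59305 spots that were no controls, at signals of 169 for control and 190 for N2ICD. Control spots and 215 spots flagged as non-uniform or as population outliers on either array were left out, and spots of one probe were averaged, which left 55672 probes. The array design repeats part of its probes, and those gave the spot noise. A gene's value was the mean over its probes well above background on both arrays. A gene well above background on 1 array alone was given as a bound: the brighter array's value over the higher of the dim probe's own value and the lowest value among probes well above background. Such a bound is at least the stated fold only if background was judged rightly. Genes were named through the probe's accession and a reference table of assembly GRCm38.p6 where the accession matched 1 symbol, which held for 31161 spots and changed the name of 1900, and by the name in the files otherwise. The reference was used for names alone. Probes for lincRNA regions and probes without any gene name were left out of the gene counts.

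With 1 array per group there was no test. Genes were counted at a 2-fold difference. The 27 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. For each list with at least 4 measured genes, the median log2 difference was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean level. A list outside percentiles 2.5 to 97.5 is called outside the random range, as a description of these 2 arrays, since genes are not replicates. With 26 lists placed, about 1 in 20 would lie outside by chance if genes varied independently of each other. The random lists hold unrelated genes, so lists of genes that vary together can lie outside more often. Named genes were 14 genes fixed by name, and, in each direction, the 10 largest differences by a size rule and the 3 largest bounds. Up to 4 measured members of each list with the largest absolute difference were named too. The size rule asked that a gene's probes well above background on both arrays all passed 2-fold the same way. A gene with 1 such probe met it with that probe alone. Gene models without a proper symbol were left out. Some genes that met these rules are not reported here. The list examples Myl2, Myl3, Tnnc1, Tnni1, Tnnt1, Casq2, Mylk2, Dll4 and Rbpj were chosen after their values were seen.

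The alternatives fixed beforehand were normexp background correction (offset 50) on the spot mean and local background, median scaling, quantile normalization, loess on signal level, a looser or no filter on dim probes, the brightest probe of each gene, the authors' deposited fold changes, thresholds of 1.5-fold and 4-fold, random lists not matched on level, and means in place of medians. Added after the data were seen were a scale set by the E1A spike-in spots (7 probes well above background on both arrays), a 75th percentile over spots well above background on both arrays, and random lists drawn from the 50 genes nearest in level. The steps were tested on simulated data: 200 of 13669 genes were changed in arrays with the measured spot noise. For changes of 1.5 on the log2 scale 99% were recovered at 2-fold and for changes of 3 all were, and 3 of 13441 unchanged genes passed. A list shifted by 0.3 was placed at percentile 100, and 1 of 25 unchanged lists fell outside the random range. The simulated noise was spot noise alone, drawn independently for each spot. These rates therefore do not say how many genes or lists would differ between animals of one group. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and limma 3.58.1.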

Results

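Gene expression was measured in tibialis anterior muscle, a mostly fast-twitch muscle of the lower leg, of adult male C57BL/6 mice. The set held 2 arrays, with 1 control sample and 1 sample from a mouse carrying the activated intracellular part of the receptor Notch2 (N2ICD) as a transgene. The series title ties Notch2 in muscle fibres to muscle mass and fibre types, and the comparison asked how the transcripts of the N2ICD muscle differed from those of the control muscle. Of 59305 spots that were no controls, 24916 were well above background on the control array and 24982 on the N2ICD array, and none was saturated. With 1 array per group no difference had a replicate check, so no p-values were computed, and genotype, animal, dissection and array could not be told apart. The single number of arrays limits the precision. Values are log2 differences, N2ICD minus control, after scaling each array to its 75th percentile. The SD of this difference between spots of one probe was 0.16 over 238 probes printed several times, from 0.27 in the dimmest of 4 level groups to 0.06 in the brightest. This is spot noise only, without any spread between animals. Different probes of one gene had an SD of 0.25.

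Notch2 was read by 2 probes, which gave different values. The probe at position 7448 of the transcript (mm9, chromosome 3, 97951233 to 97951292) had a signal of 221 on the N2ICD array and 6.01 on the control array, where it was not well above background, so the N2ICD level was at least 7.72-fold higher, a log2 bound of 2.95 that was 1.52 after normexp background correction. The probe at position 10129, nearer the 3′ end (chromosome 3, 97953914 to 97953973), had signals of 189 in control and 179 in N2ICD, a log2 difference of -0.25, which lies within 2 SD of the spot noise and turned to 0.28 on a scale set by the spike-in controls. The labels do not say whether the transgene carries the 3′ part of the transcript. Each probe had 1 reading frame with 0 stop codons, so this did not separate them. Frames of 19 and 20 codons are too short for such a test to decide. The probes were not placed in coding sequence or untranslated region.

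Among direct transcriptional targets of Notch, Hes1 (chromosome 16, 30067820 to 30067879), a basic helix-loop-helix repressor, was 5.59-fold higher in the N2ICD array, with signals of 55.4 in control and 348 in N2ICD. Nrarp, a feedback inhibitor of Notch, was 1.92-fold higher, Heyl 1.61-fold and Hey1 1.45-fold. Hes5 was well above background on the control array alone, with signals of 31.2 in control and 19.4 in N2ICD. Of the 13 measured Notch targets and components, 1 was at least 2-fold higher, 0 were 2-fold lower and 12 lay between. The 9 others ran from -0.34 for the ligand Dll4 to 0.06 for Rbpj, and the list median of 0.02 stood at percentile 62.0 of 10000 random lists matched on level. The mean of the same list was 0.31, at percentile 99.4 of random means.

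Of 13669 genes measured on both arrays, 195 were at least 2-fold higher and 122 at least 2-fold lower in the N2ICD array, together 2.32% of the genes. At least 4-fold differences were seen in 20 genes upwards and 9 downwards. Igfn1 (chromosome 1, 137852383 to 137853282), an immunoglobulin-like and fibronectin domain protein of the sarcomere, differed most among genes named by the size rule and was 19.5-fold higher, with signals of 35.8 and 785. Mss51, a mitochondrial protein of skeletal muscle, was 12.3-fold higher and Tceal7 11.5-fold, with N2ICD signals of 12831 and 22062. The next were Col9a1 (5.82-fold), Rsph1 (5.54-fold), the stress-responsive factor Atf3 (5.35-fold), the immediate early gene Fos (5.07-fold), Tmem100 (4.92-fold) and the slow myosin heavy chain Myh7 (4.64-fold). Tceal7, Col9a1 and Rsph1 each had another probe that was not well above background on either array. In the other direction Actc1 (chromosome 2, 113873064 to 113873123), the cardiac alpha-actin that skeletal muscle also makes during development, was 16.3-fold lower, with signals of 19171 in control and 1327 in N2ICD. Mybph, a myosin-binding protein, was 8.37-fold lower, the small G protein Rasd2 6.90-fold and the carboxylesterase Ces1d 6.77-fold. They were followed by Lrtm1 (4.49-fold lower), Cbr2 (4.19-fold), the Wnt antagonist Frzb (4.18-fold), Il4i1 (3.76-fold), the kinase Pak1 (3.76-fold) and the peptide hormone Apln (3.44-fold). Apart from Cbr2 (2 probes) and Fos (10 spots of 1 probe), each fold named here rests on 1 measured probe with 1 spot per array.

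A further 492 genes were well above background on the N2ICD array alone and 479 on the control array alone. Their differences are bounds, and 45 and 61 of them reached 2-fold. Gdf11 (chromosome 10, 128322284 to 128322343), a growth factor of the TGF-beta family and close relative of myostatin, was at least 28.9-fold higher in the N2ICD array, with a signal of 827 against 8.98. Mat1a, a methionine adenosyltransferase best known from liver, was at least 14.9-fold higher and Efcab12 at least 6.02-fold. Ifitm10 was at least 5.21-fold lower and Adam26a at least 4.20-fold. Efcab12, Ifitm10 and Adam26a each had another probe that was not well above background on either array. Of the 39 genes past 2-fold with several measured probes, 23 had all probes past 2-fold the same way. Of all 3162 genes with several probes, 19 had a probe past 2-fold beside another of opposite sign. The counts depended on the processing. Normexp background correction gave 82 genes higher and 43 lower, probes above background on at least 1 array gave 365 and 328, and no filter on dim probes gave 836 and 968. A scale set by the spike-in controls, chosen after the data were seen, moved all genes up by 0.52 and gave 1065 higher and 22 lower, so that 98.0% of the 2-fold genes were higher against 61.5% in the main setting, 52.7% with the looser filter and 46.3% with none. All directions given here are relative to the typical gene, whose log2 difference was 0.01.

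Genes of the slow contractile apparatus were higher in the N2ICD array. Of 15 measured, 13 were above 0, 5 of them at least 2-fold, and the list median was 0.76, at percentile 100 of random lists matched on level. Myh7 was 4.64-fold higher, with signals of 154 and 805. The Z-disc protein Myoz2 was 3.49-fold higher, the muscle LIM protein Csrp3 3.37-fold and the ankyrin repeat protein Ankrd2 2.30-fold. Myl3, the slow essential light chain, had a log2 difference of 0.96, and the slow troponins Tnnc1, Tnni1 and Tnnt1 had 0.99, 0.65 and 0.54. The slow regulatory light chain Myl2 went the other way, at -1.15, and the calcium-binding protein Casq2 lay at -0.60.

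Genes of the fast contractile apparatus were slightly lower, at a list median of -0.26 (percentile 0.06), which turned to 0.27 on the spike-in scale. None of the 15 passed 2-fold, and 13 lay below 0. Casq1 had -0.55, Mylpf -0.47, the calcium buffer parvalbumin (Pvalb) -0.42 and Mybpc2 -0.36. Among the adult fast myosin heavy chains, Myh2 (type IIa, chromosome 11, 67010960 to 67011019) was 2.46-fold higher, with signals of 65700 and 182477. Myh1 (type IIx) lay at 0.03 and Myh4 (type IIb) at -0.26, or 0.27 on the spike-in scale. The slow median exceeded the fast median by 1.02 on the log2 scale, at percentile 100 of 10000 pairs of random lists, whose middle 95% ran from -0.22 to 0.19. After normexp background correction the slow median was 0.49 and the difference 0.65, both at percentile 100. When each random member was drawn from the 50 genes nearest in level, chosen after the data were seen, the fast median stood at percentile 4.40, inside the random range. The slow minus fast difference stayed at percentile 100.

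**Figure D1:**
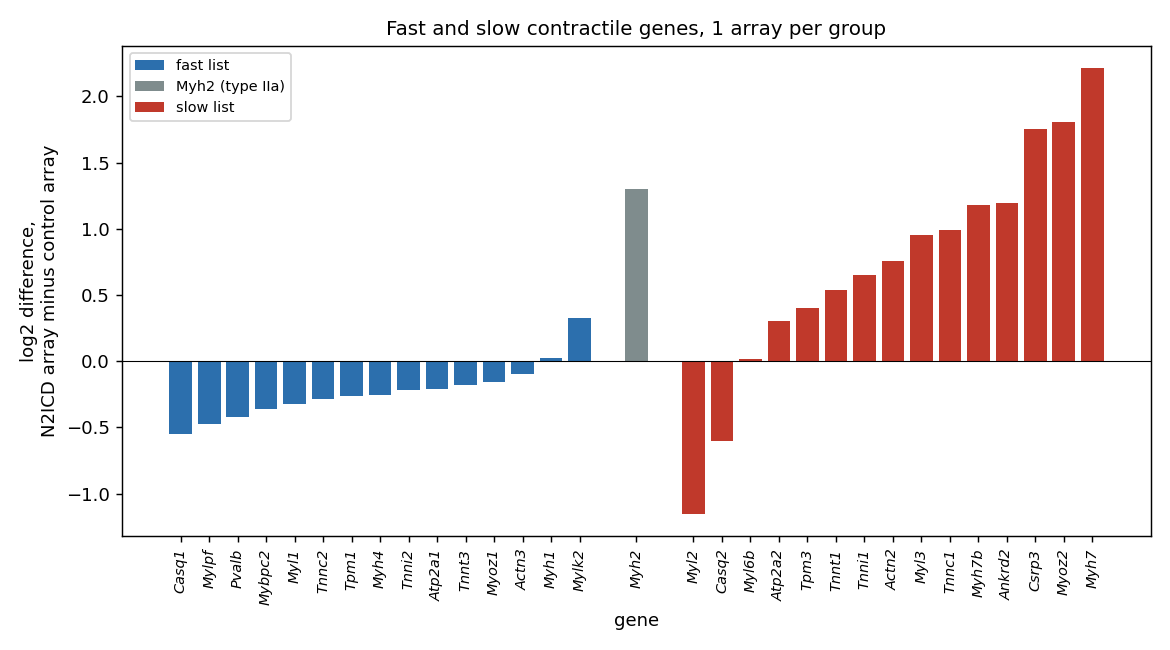
Bars give the log2 difference between the N2ICD array and the control array (y axis, log2 units) for each measured gene (x axis) of the fast list (blue), for Myh2 (grey) and for the slow list (red), with 1 array per group and no error bars. Slow genes run from -1.15 for Myl2 to 2.21 for Myh7, and fast genes from -0.55 for Casq1 to 0.32 for Mylk2; a scale set by the spike-ins adds 0.52 to each bar and turns the fast median to 0.27.

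Developmental sarcomere genes had a median of -0.32 over 7 measured genes (percentile 0.645), which turned to 0.20 on the spike-in scale. This list was led by Actc1 at -4.03 and Mybph at -3.07, while Tnnt2 had 0.48 and the perinatal myosin Myh8 -0.45, the mean of -0.24 and -0.66 in 2 probes, with its other 2 probes not above background on either array. The brighter Myh8 probe had a control signal of 490871, above the 339444 of Myh4, and whether it reads Myh8 alone was not tested. With no filter on dim probes its median stood at percentile 12.5, and with the brightest probe of each gene at 2.54. Myogenic regulators had a median of 0.11 (percentile 88.6), with Mef2c at 0.67, Id1 at -0.50, Myog at 0.43 and Id3 at -0.30, and 0 of 12 passed 2-fold. Satellite cell markers had a median of 0.12 (percentile 84.8). Among them the laminin receptor Itga7, which muscle fibres also make, was 2.81-fold higher, and Sdc4 had 0.86 and Cdh15 0.73. Their mean of 0.32 stood at percentile 98.9.

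Glycolysis and glycogen genes were lower in the N2ICD array, with a median of -0.29 over 17 genes, at percentile 0 of random lists, and at 0.23 on the spike-in scale. Of them 15 lay below 0 and 0 passed 2-fold. The muscle fructose bisphosphatase Fbp2 had -0.98, the phosphorylase kinase subunit Phka1 -0.69, the muscle glycogen phosphorylase Pygm -0.43 and Gpd1 -0.43. Genes of oxidative phosphorylation had a median of 0.05 over 28 genes (percentile 68.7) and none passed 2-fold. The outermost members were Cycs at 0.30, Ndufa4 at 0.28, Ndufb5 at 0.26 and Cox6a2 at -0.23. Fatty acid oxidation genes had a median of 0.04 (percentile 47.3), with the acylcarnitine carrier Slc25a20 at -0.71 and the fatty acid-binding protein Fabp3 at -0.67. The lipoprotein lipase Lpl was 2.06-fold higher, the mean of 2 probes at log2 differences of 1.44 and 0.65. Regulators of mitochondrial biogenesis had a median of 0.24 over 11 genes (percentile 98.7, or 96.7 after normexp background correction). The nuclear receptor Esrrg had 0.83, the coactivator Ppargc1a 0.62, Tfam 0.30 and Prkaa2 0.29.

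Muscle atrophy genes had a median of 0.19 over 19 genes (percentile 99.0), with 2 at least 2-fold higher and 16 above 0. Those 2 were the metallothioneins Mt2 (3.64-fold) and Mt1 (2.21-fold), which bind metals and also respond to stress and glucocorticoids. Myostatin (Mstn), a secreted inhibitor of muscle growth, was 1.86-fold higher, and the translation repressor Eif4ebp1 was 1.63-fold higher. The muscle ubiquitin ligase Fbxo32 had 0.38, with an SD of 0.05 over 10 spots, and Trim63 had 0.09 over 2 probes that gave 0.24 and -0.06. Proteasome subunits had a median of 0.15 (percentile 98.6), with 22 of 26 above 0. Their percentile was 95.8 after quantile normalization, 97.4 after normexp and 97.0 with means. Psmc6 had 0.62, Psma4 0.35, Psma7 0.32 and Psmd14 0.28. Ribosomal protein genes had a median of 0.14 (percentile 98.8), with Rpl14 at 0.39, Rpl4 at 0.38, Rpl30 at 0.23 and Rps9 at 0.23. This percentile was 95.3 with no filter on dim probes, and 96.0 both with means and among the genes nearest in level. IGF and growth signalling genes had a median of 0.08 (percentile 80.7), with Smad3 at 0.67, Igfbp4 at -0.66, Rps6kb1 at 0.63 and Smad7 at 0.59. Denervation and synapse genes had a median of -0.06 (percentile 35.0) and a mean of 0.10. Among them the synaptic kinase Musk was 4.32-fold higher, while Gadd45a had -0.66 and Runx1 0.65.

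Immediate early and stress genes had a median of 0.94 over 12 measured genes (percentile 100). Members above 0 numbered 8 and those below 0 numbered 4, and 6 were at least 2-fold higher and 0 at least 2-fold lower. Atf3 was 5.35-fold higher, Fos 5.07-fold with an SD of its log2 difference of 0.12 over 10 spots, Egr1 4.50-fold and Fosb 2.44-fold. Circadian clock genes had a median of -0.28 over 14 genes (percentile 0.18), and 0.25 on the spike-in scale. Of them 8 lay below 0, 6 above, and 0 passed 2-fold. The activator Arntl had 0.93, while Ciart had -0.87, Bhlhe41 -0.79 and Per3 -0.69. Another Bhlhe41 probe was well above background on the control array alone, with signals of 135 in control and 27.7 in N2ICD. It was at least 5.50-fold lower and did not enter the gene's value. With the mean in place of the median the clock list stood at percentile 5.82. Unfolded protein response genes had a median of 0.04 (percentile 55.4). In that list Chac1, which degrades glutathione, was 2.11-fold lower, and Hsp90b1 had 0.51, Dnajb9 0.42 and Xbp1 0.41. Interferon response genes had a median of -0.09 (percentile 24.6), with Gbp2 at 0.63, Usp18 at -0.63, Rtp4 at 0.49 and Oasl2 at -0.23.

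Extracellular matrix and fibroblast genes were lower in the N2ICD array, with a median of -0.28 over 18 genes, at percentile 0, which turned to 0.25 on the spike-in scale. None passed 2-fold and 15 lay below 0, led by Col5a2 at -0.67, the protease inhibitor Timp1 at -0.62, Col5a1 at -0.46 and Col6a1 at -0.45. These genes, which mark a cell type other than the muscle fibre, went the same way as the fast contractile and glycolysis genes. Macrophage and leukocyte markers had a median of -0.16 (percentile 5.61), with Csf1r at -0.61, Cd68 at -0.44, Tyrobp at -0.42 and Lyz2 at 0.40. Endothelial markers had -0.10 (percentile 7.85), with Emcn at -0.59, Kdr at -0.52, Tek at -0.34 and Esam at -0.34. Smooth muscle and pericyte markers had 0.07 (percentile 67.2), with Cspg4 at 0.75, Smtn at 0.35, Myh11 at 0.26 and Acta2 at -0.22. Schwann cell and nerve markers had 0.04 (percentile 68.0), with Ncmap at 0.86, S100b at 0.78, Sox10 at -0.32 and Prx at 0.26. Erythroid markers had -0.08 (percentile 18.4), with Slc4a1 at -0.67, Bpgm at -0.20 and Hbb-b1 at -0.16. Adipocyte markers had a median of -0.01 (percentile 43.8) and a mean of 0.10, with Car3, which muscle also makes, at 0.87, Cidec at 0.37, Fabp4 at 0.37 and Plin1 at -0.30. Of the 4 Y-linked genes 2 were measured on both arrays, Ddx3y at 0.85 and Eif2s3y at 0.51.

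**Figure D2:**
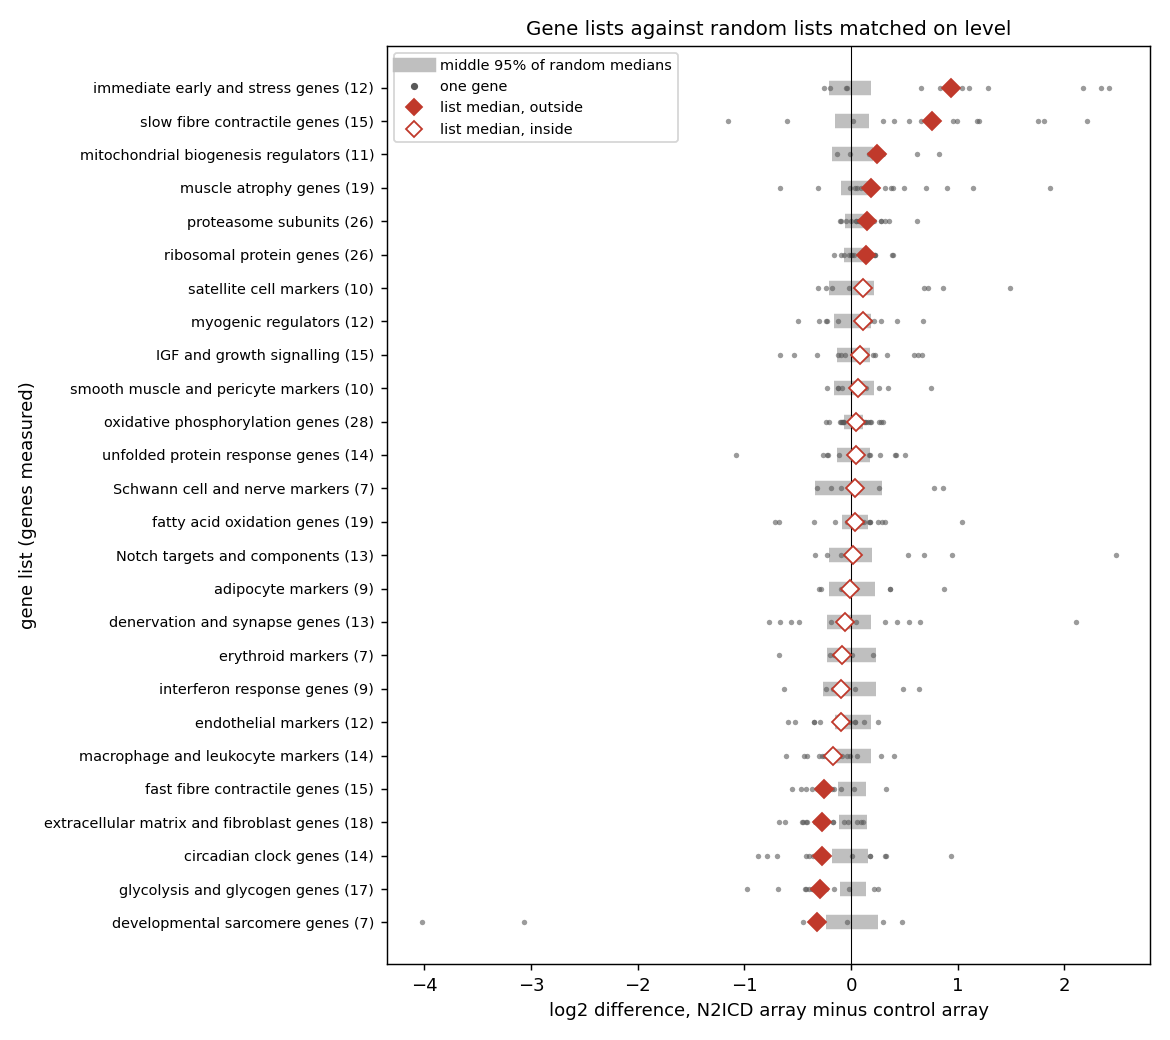
Each line is a gene list (y axis, with the number of measured genes), with the log2 difference between the N2ICD and control arrays on the x axis (log2 units); dots are genes, diamonds list medians, and grey bars the middle 95% of medians of 10000 random lists matched on level. Filled diamonds mark the 11 lists outside that range, 6 above it and 5 below it, and a scale set by the spike-ins moves every value up by 0.52 and puts the medians of those 5 lists above 0.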

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

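The tests of slow muscle share were chosen after the result was seen, and the others in this part were fixed before their values were known. Outside the gene comparison, 3154 probes for lincRNA regions were well above background on both arrays, and 52 of them were at least 2-fold higher in the N2ICD array than in control, while 78 were at least 2-fold lower. The largest higher value was 3.59-fold, at chromosome 18, 6201050 to 6201109 (mm9), and the largest lower one 6.35-fold, at chromosome 6, 145695157 to 145695216. Of 965 probes without a gene name, 10 were at least 2-fold higher in the N2ICD array and 10 at least 2-fold lower. The highest was 9.29-fold, at chromosome 11, 99557623 to 99557682, with signals of 55.2 and 578.

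The slow contractile genes stood higher and the fast ones slightly lower in the N2ICD array. A larger share of slow muscle in the N2ICD piece stays open: Myl2, itself a slow isoform, differed by -1.15, but the spread between animals or pieces was not measured. A trend with signal level between the arrays would be removed by loess, but the slow minus fast difference was 1.04 after it. That value covers the difference alone. The fast median itself, as given above, lay inside the random range among the genes nearest in level (percentile 4.40). A trend with level thus stays open for the fast genes. A shift of fibre type with the transgene may account for the pattern as a hypothesis, and it stays untested because genotype and animal coincide.

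Immediate early genes had a higher median, with 8 of 12 above 0. The clock genes had a lower median with 6 of 14 above 0 and a mean at percentile 5.82, inside the random range. Both could reflect the moment of harvest. For time of day, clock outputs outside the fixed list were read: Nfil3 minus the mean of Usp2 and Wee1 was 0.19, between the bounds of 0 and 0.5 set beforehand. For handling or delay, 14 other fast response genes had a median of 0.42, at percentile 100 of random lists, with Ccn1 at 1.56, Socs3 at 1.11 and Csrnp1 at 1.11. That lies above the lower bound of 0.2 and short of 0.5. Time of day, handling and genotype cannot be told apart with 1 animal per group.

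Genes 2-fold apart might include passengers of another strain's genome. Along mm9, 172 of 315 such genes with a position had another within 2 Mb, against a median of 163 in random sets, whose random range reached up to 182. The count, taken without regard to direction, stayed inside the random range and so gave no sign of concentrated strain stretches. It does not exclude them. The count cannot show differences spread over the whole genome, and its power was not measured. The largest run held 8 genes on chromosome 17, and 24.5% of random sets held one as large. Nnt, which carries a deletion in C57BL/6J and not in C57BL/6N, was read by 1 probe well above background and differed by -1.17 (signals 1089 and 545). The other 2 Nnt probes were not above background on either array (5.85 and 8.17, 5.47 and 5.84). A difference of substrain between the mice stays a candidate explanation for Nnt and was not tested for other single genes, Wdfy1 among them. The read Nnt probe was not placed against the deletion and remained well above background in N2ICD. An effect of the transgene on Nnt stays open too.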

How the results depend on the processing

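The spike-in scale, the scale over spots above background and the matching to the 50 nearest genes were chosen after the data were seen. The cause of the changes below was not tested, except that a lower or higher threshold and a looser filter count more or fewer genes by construction. The normexp offset of 50, added to each signal, also shrinks the log2 differences of dim probes by construction. How much of the normexp changes came from this offset was not tested. No paired analysis was possible because each group holds 1 sample. Counts of genes at least 2-fold higher and lower, 195 and 122 in the main setting, were 82 and 43 with normexp (81 and 43 of them shared), 365 and 328 with probes above background on at least 1 array, 836 and 968 with no filter, 695 and 662 at 1.5-fold, and 20 and 9 at 4-fold. They were 1065 and 22 on the spike-in scale, and within 1.5 times the main counts in the other settings. With normexp, the Notch2 bound was 1.52 (main 2.95), the slow median 0.49, the immediate early median 0.65 and the slow minus fast difference 0.65. The authors' deposited fold change put the Notch2 probe at 5.04, with no bound applied. With no filter the medians of developmental sarcomere genes, myogenic regulators and satellite cell markers were -0.13, -0.0724 and -0.0587. Means in place of medians gave 0.31 for Notch targets, -1.02 for developmental sarcomere genes, 0.32 for satellite cell markers and 0.10 for denervation genes. The spike-in scale turned the sign of every list median below 0, also for denervation, macrophage, endothelial, adipocyte, erythroid and interferon genes. It put the 5 medians below the random range at 0.27 (fast fibre), 0.20 (developmental sarcomere), 0.23 (glycolysis), 0.25 (extracellular matrix) and 0.25 (clock). It put the others at 0.54 (Notch), 1.28 (slow fibre), 0.64 (myogenic), 0.64 (satellite), 0.71 (atrophy), 0.46 (denervation), 0.61 (IGF), 0.67 (proteasome), 0.57 (oxidative phosphorylation), 0.56 (fatty acid oxidation), 0.76 (mitochondrial biogenesis), 0.36 (macrophage), 0.43 (endothelial), 0.59 (smooth muscle), 0.52 (adipocyte), 0.56 (Schwann), 0.44 (erythroid), 1.46 (immediate early), 0.66 (ribosomal), 0.57 (unfolded protein) and 0.43 (interferon), and the Notch2 probes at 3.47 and 0.28. Being one constant, it left the slow minus fast difference at 1.02. Of 1240 values of 124 named genes under the alternatives, 1053 lay within 1 SD of spot noise of the main value. The other 187 lay further away. From beyond 2-fold 0 changed sign, and 2 of 32 genes past 2-fold dropped below it somewhere. The spike-in scale moved each value by 0.52, too little to turn a gene past 2-fold. Values nearer 0 that turned are not in that count, such as the Notch2 probe at position 10129 (-0.25 to 0.28 on the spike-in scale). Signal over background limits dim genes: the spot noise was 0.27 in the dimmest of 4 level groups of repeated probes.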

Other observations

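Gdf11 and Itga7 lie close together on chromosome 10, and both were higher in the N2ICD array. The choice of this region was made after its values were seen. The Itga7 probe lies 72.9 kb from the Gdf11 probe (mm9) and had a log2 difference of 1.49, with signals of 8493 and 26853. The genes read between them lay nearer 0, with Cd63 at 0.37, Rdh5 at -0.07 and Bloc1s1 at 0.02 and 0.11 in 2 probes. On the other side Sarnp had 0.27, and Dnajc14 had 0.03. Gdf11 was read by a single probe.

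Wdfy1, an adaptor of endosomal signalling, was among the genes whose probes disagreed, and was picked after its values were seen. The probe at chromosome 1, 79698903 to 79698962 was 7.60-fold higher in the N2ICD array, with signals of 74.3 and 636. The probe at 79723062 to 79723121 had signals of 710 and 863 and a log2 difference of 0.11, and the neighbouring probe at 79723042 had -0.29. A further probe at 79699969 to 79700028 was above background on the N2ICD array alone, with signals of 13.9 and 62.1. No cause of this split was tested, and a difference of substrain between the mice was not excluded for Wdfy1.

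Several Z-disc genes of the slow list were higher, and Z-disc and costamere genes outside the fixed lists were tested as a set, with the bound written before their values were seen. The hypothesis that they were higher together was not borne out. The median over 27 measured genes was 0.10, at percentile 90.3 of random lists. Within the set Xirp1 had 1.34, Hspb7 1.20, Dmd 0.69 and Flnc 0.59, while Pdlim7 had -0.40 and Hspb8 -0.37.

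The spike-in transcripts were lower on the N2ICD array than the scaled genes, from -0.37 to -0.57 over 7 probes. A different amount of RNA in the labelling or a different messenger content may underlie this shift of 0.52, which gave 1065 genes higher, and no test here separates them. Xist was not well above background on either array.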
